A study of Homo sapiens with 36 samples.

How the data were processed

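The series holds 36 libraries of enhanced crosslinking and immunoprecipitation (eCLIP) from HEK293T cells, a human embryonic kidney line that is easily transfected. Per the labels, 9 proteins were assayed, each with 2 immunoprecipitated (IP) libraries and 2 matched input libraries, and the cells received no further treatment. Per the labels' protocols, cells were lysed and sonicated, RNA was fragmented with RNase I, and complexes were recovered with an antibody against the protein itself or against a V5 tag. Which antibody served which protein is not stated. Each protein and library type was treated as a group, which gave 18 groups of 2. The labels do not say whether replicates were separate cultures, so the spread between them may be technical.

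The authors deposited 9 tables, one per protein, of windows called enriched in the IP over the input. The genome build was hg38, per the submitters' processing notes, and coordinates are given 1-based in that build. The aligner, the window caller and the annotation version are not given in the sources used here. The deposited read counts are whole-number IP and input counts per window that the authors summed over the replicates, so no count per library was available for a test. The log2 enrichment of IP over input, per the file headers a log2 odds ratio, was deposited by the authors as a lower, mean and higher value over replicates. It is the authors' own value, its model and baseline are not given in the sources used here, and it was used only to describe, rank and filter windows within a list. The authors also deposited the lowest and highest p-value and q-value of each window over the replicates. The GC fraction of each window was deposited by the authors and is printed as a percentage. Every listed window was called in 2 replicates, and the largest q-value in any table was 0.1999. The mean enrichment was the midpoint of the lower and higher value in every window. Windows were at most 100 nt long, each carried 1 of 18 feature types from the authors' annotation, and adjoining windows were counted separately.

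Library depth is unknown, because the tables hold only reads in listed windows. Between 187076 (LGALS3) and 13313477 (GRB2) IP reads and between 65036 (LGALS3) and 1548461 (CPSF6) input reads fell in listed windows. List lengths reflect depth and antibody as well as binding, and were not tested against each other. A window missing from a list was either not enriched or not covered well enough, and the tables cannot separate these. The p-values and intervals below cover variation among the genes or windows of these lists, not among cultures.

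All values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. The 18 feature types were grouped into 13 classes. Intron windows in the 100 nt next to a splice site were called adjacent, those in the rest of the 500-nt flank proximal, and those farther away deep intron. Shares of classes were given with 95% intervals from 1000 resamples of genes, and pairs of lists were compared by swapping each gene's windows between the lists at random in 2000 permutations. Each list was then described by the class in which it exceeded the mean of the other 8 lists by most points. That rule was chosen after the values were seen, since the largest class of the RBM22 list was below the mean of the other lists.

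For distances to transcript ends, the deposited window numbers were used to rebuild the number of windows in each 3' UTR. A 3' UTR was kept where its end lay within 100 nt of the end of the gene in the RefSeq gene table for GRCh38.p14, the only reference used here. The share of windows centred within 200 nt of that end was compared with even placement in the same 3' UTR (1000 placements, two-sided permutation test). For splice sites, the share of flank windows in the adjacent 100 nt was compared with an even share of 20%, and coding windows at the first and last place of an exon with even placement in that exon. These comparisons departed from the plan, which assumed exon coordinates. Windows of short introns that lie in the flanks of both splice sites were left out. An even spread can therefore leave more than 20% adjacent where introns are short, and excesses over 20% may be overstated. Windows could be placed only where the next annotated feature also held a listed window, and neighbouring windows are not independent, so these p-values are smaller than independent windows would give. A search for poly(A) signals and binding motifs needs genome sequence and was not analysed here.

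Overlap of 2 lists was measured as an odds ratio over windows listed for at least one of the other 7 proteins, with 95% intervals from 200 resamples of genes and Fisher's exact test over 36 pairs. The same was done over genes. Gene lists were fixed before the data were examined. They covered cleavage and polyadenylation factors, SR proteins, hnRNP proteins, the exon junction complex with nonsense-mediated decay, core spliceosome proteins, translation initiation factors, ribosomal proteins, replication-dependent histones, chaperones, glycolysis, genes reported to change poly(A) site with CFIm, MBNL targets, nuclear long noncoding RNAs, small nuclear and 7S RNAs, mitochondrially encoded genes and the genes of the assayed proteins. For each list, the share of members with an enriched window was compared by two-sided Fisher's exact test with all genes listed for at least one of the other 8 proteins, and again by permutation against genes matched in 20 bins on their number of windows in the other lists. Adjusted p-values are Benjamini-Hochberg values over each family of tests.

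Genes were named by a rule fixed before the data were examined. For each protein it took the 6 genes with the highest lower-replicate enrichment among windows with a q-value of at most 0.05 in both replicates and at least 20 IP reads, the 6 genes with most windows, the 3 strongest members of each gene list, and the genes of the assayed proteins. The X-inactivation transcript was left out of the naming. Histone, ribosomal protein, small nuclear RNA and other multi-copy genes share reads with near-identical copies, so their values are uncertain.

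Each procedure was tested on simulated data in which windows or genes were drawn independently. Error rates under clustering of windows within genes or uneven coverage were therefore not tested. For the composition test, the MBNL2 list was split at random into 2 lists of about equal length. That test made 0 calls among 260 comparisons with no planted difference and found the planted one in 20 of 20 simulations. Lists of very unequal length were not simulated, so these counts do not cover comparisons of a short with a long list. The test for 3' UTR ends made 2 calls in 100 null simulations of the CPSF5 list and 100 in 100 planted ones, and the splice site test 6 and 100. Overlap intervals held the true odds ratio in 49 of 50 null and 45 of 50 planted simulations. The gene list test called 0 of 100 random and 20 of 20 planted lists, and the matched test 0 of 100 random lists. Alternatives tried were stricter q-values, minimum enrichment and read counts, merged windows, weighting by genes or reads, other distances, other backgrounds and matching. Leaving out the assayed proteins' own genes, or windows strongly enriched in several lists, was added after seeing the data.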

Results

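Binding of 9 proteins to RNA was mapped by eCLIP in HEK293T cells, in a series that followed a tethered screen for regulators of poly(A) site choice. CPSF5 (gene NUDT21) and CPSF6 are subunits of cleavage factor Im (CFIm), which binds upstream of poly(A) sites. RBM10, RBM22 and RNPS1 act in splicing or in the exon junction complex, and MBNL2 is a muscleblind splicing regulator. EIF4B helps the EIF4A helicase at the 5' ends of mRNAs. GRB2, a signalling adaptor, and LGALS3, a galactoside-binding lectin, are better known for functions outside RNA metabolism. Each protein had 2 IP and 2 input libraries, and each list holds the windows that the authors called enriched in both replicates. Which transcripts and which parts of them each protein bound, how far the lists overlapped, and how windows lay relative to transcript ends and splice sites were compared across the 9 lists.

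GRB2 had the longest list, with 291116 windows in 5278 genes, and LGALS3 the shortest, with 1002 windows in 369 genes. CPSF6 had 155533 windows in 9519 genes, RNPS1 152730 in 9833, EIF4B 68716 in 10084, MBNL2 42960 in 7028, CPSF5 38826 in 6904, RBM10 28544 in 5095 and RBM22 8671 in 2619. The lists held 788098 windows in all and 601384 distinct ones, and 77.7% of the distinct windows were in 1 list only. The log2 enrichment over input, the authors' own value, had a median in the lower replicate between 2.12 (RBM22) and 3.38 (GRB2). The median gap between replicates was 0.64 for RBM22 and LGALS3, 0.86 for RNPS1, and largest for RBM10. Median IP reads per window, summed over replicates, ranged from 24 (MBNL2) to 46 (EIF4B). GRB2 windows had a median of 1 input read and 36.8% had none, so single enrichment values of that list rest on few input reads. In the LGALS3 list, 10 windows held 46.7% of the IP reads, against 1.64% in the GRB2 list.

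CPSF5 windows lay in 3' UTRs. That class made up 78.8% of the CPSF5 list (95% interval over genes 77.9 to 79.8), against 19.7% for MBNL2, the next highest list, and a mean of 7.58% over the other 8 lists. The strongest CPSF5 windows in 3' UTRs were in SDE2 (chromosome 1, 225983002 to 225983101), C5orf15 (chromosome 5, 133956762 to 133956858) and TRUB1, a pseudouridine synthase gene (chromosome 10, 114977277 to 114977376). They held 493, 218 and 236 IP reads and no input read, and their lower-replicate log2 enrichments were 9.04, 8.05 and 7.96. The most windows per gene were in SLIT2, a secreted guidance factor gene, with 72, followed by LNPEP with 58, CAPN15 with 56, SPEN and HOXC6 with 50 each, and POMK with 49. CPSF6, a partner subunit, had only 7.26% of its windows in 3' UTRs (interval 6.94 to 7.59), while 46.3% were in coding sequence and 23.4% in deep introns. The difference between the CPSF5 and CPSF6 lists was 71.6 points for 3' UTRs (adjusted permutation p = 0.00057).

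EIF4B windows were most distinct in 5' UTRs, which held 30.6% of them (interval 29.9 to 31.2) against 11.1% for MBNL2, the next highest list. A further 10.3% covered start codons, and the median lower-replicate log2 enrichment was 3.69 in 5' UTRs and 2.39 in coding sequence. Strong examples were the 5' UTR of the histone gene H2BC13 (chromosome 6, 27807907 to 27807931), with a log2 enrichment of 8.25 in the lower and 8.29 in the higher replicate, and that of ANKRD11, a chromatin regulator gene with 139 EIF4B windows. The strongest EIF4B window, at 8.92, was a 2-nt stretch of a noncoding exon of AHCY (chromosome 20, 34303356 to 34303357). FBRSL1 and GSE1 had the most EIF4B windows, 229 and 191, and their strongest windows were intronic. MACROD1 had 91 and UCKL1 103.

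GRB2 windows were intronic. Deep introns made up 93.1% of the list (interval 92.7 to 93.5), against 23.4% for CPSF6, the next highest list, and coding sequence only 0.0794%. The most windows were in long genes, with 1776 in DOCK3, 1503 in ANKRD11, 1496 in AUTS2, 1146 in DIP2C, 1067 in TTC28 and 1042 in SMYD3. Strong examples were introns of CUL4A, a ubiquitin ligase scaffold gene (chromosome 13, 113214964 to 113215062), with 521 IP reads and no input read, SIN3B (chromosome 19, 16875455 to 16875554) with 607, FANCL (chromosome 2, 58171067 to 58171165) with 608 and SOD2 (chromosome 6, 159711131 to 159711230) with 503. Their lower-replicate log2 enrichments ran from 8.66 to 8.93.

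The splicing proteins RBM10 and RBM22 were set apart by windows next to splice sites. RBM10 had 32.0% of its windows adjacent to 3' splice sites (interval 31.0 to 33.1), against 4.25% for RNPS1, the next highest list, and a further 16.5% in the rest of the splice site flanks. Examples were DTNA (chromosome 18, 34858185 to 34858284) with 278 IP reads at a 3' splice site, HUWE1, with 70 IP reads and no input read, and HNRNPA1, a splicing regulator gene, where a short intron (chromosome 12, 54281952 to 54282041) reached a log2 enrichment of 7.46. NSUN6 had the most RBM10 windows, 190, followed by GSE1 with 137, HUWE1 with 110, MAD1L1 with 107, DAZAP1 with 99 and CTBP1 with 90. Further strong RBM10 windows were in MCM3AP, at 7.54, and in VCL, the vinculin gene, at 7.37. RBM22 had 20.1% of its windows adjacent to 5' splice sites (interval 18.6 to 21.8), against 6.87% for RBM10. Its largest class was coding sequence at 27.9%, which was below the mean of the other lists. SPEN had the most RBM22 windows, 118, followed by DNAH14 with 93 and MKI67 with 86. LINC00342 and AC159540.1, annotated as long noncoding RNAs, had 57 and 70, and GOLGB1 58.

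RNPS1, LGALS3, MBNL2 and CPSF6 windows were most distinct in coding sequence, with shares of 63.3%, 62.6%, 50.1% and 46.3%. RNPS1 exceeded the mean of the other lists by 34.9 points (interval 33.9 to 35.96), LGALS3 by 34.1 (27.3 to 39.5), MBNL2 by 20.1 (19.0 to 21.3) and CPSF6 by 15.8 (14.7 to 17.0). Strong RNPS1 windows were in the coding sequence of CALD1, which encodes the actin-binding protein caldesmon, at a log2 enrichment of 7.45, PDAP1 at 7.41, CBX3, a heterochromatin protein gene, at 7.39, TSPYL2 at 7.29 and LARP7 at 7.04, besides an intron of BCAS3 at 7.24. The most RNPS1 windows were in long mRNAs, with 189 in HUWE1, 182 in MDN1, 174 in PRKDC, 165 in DYNC1H1, the dynein heavy chain gene, 164 in MACF1 and 161 in MYCBP2. Genes with many LGALS3 windows included IQGAP1 with 46, AMOT with 35, CTNNB1 with 30, and SPTAN1 and SPTBN1 with 27 each. The strongest CPSF6 window was in coding sequence of RBM18 (chromosome 9, 122251847 to 122251909), with 554 IP reads, no input read and log2 enrichments of 9.35 and 9.43, followed by introns of PRKCA at 8.78 and ETV5 at 7.47 and the 3' UTR of ZNF234 at 7.22. CPSF6 had most windows in DOCK3 with 357, DST with 292, SPIDR with 263, GPHN with 253, DNAH14 with 247 and FAF1 with 230. MBNL2 had most in PRRC2B with 91, HUWE1 with 86, TMEM201 with 78, ANKRD52 with 60, PRKDC with 58 and FBRSL1 with 57. Its strongest windows included a 3' splice site of TNKS2 at 7.44, the 3' UTR of ZNF516 at 7.02 and introns of CDK17 at 7.80 and PARN at 7.56. The PARN window held 23 IP reads and was also strong for CPSF5 and GRB2. The PRKCA and ETV5 windows named for CPSF6 were also strong for EIF4B, RBM10 and RBM22. None of these shared windows touched another listed window, so they may not be particular to the protein named.

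Of 468 pairwise differences in class shares, 430 passed the permutation test after adjustment, with p-values down to 0.00050, the smallest these permutations can give. Swapping gives both permuted lists about the same length, so the test understates the sampling error of a short list. LGALS3, with 4 windows adjacent to 5' splice sites, was called below GRB2 there (0.399% against 0.507%, adjusted permutation p = 0.0039). Its interval over genes was 0.092 to 0.893%, which holds the GRB2 share. The 430 calls may therefore include differences in small classes that the intervals do not bear out. When windows were weighted by IP reads, the LGALS3 share of coding sequence lay -0.248 points from the mean of the other lists. The intervals treat genes as the unit and leave out differences in depth and antibody between proteins.

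**Figure D1:**
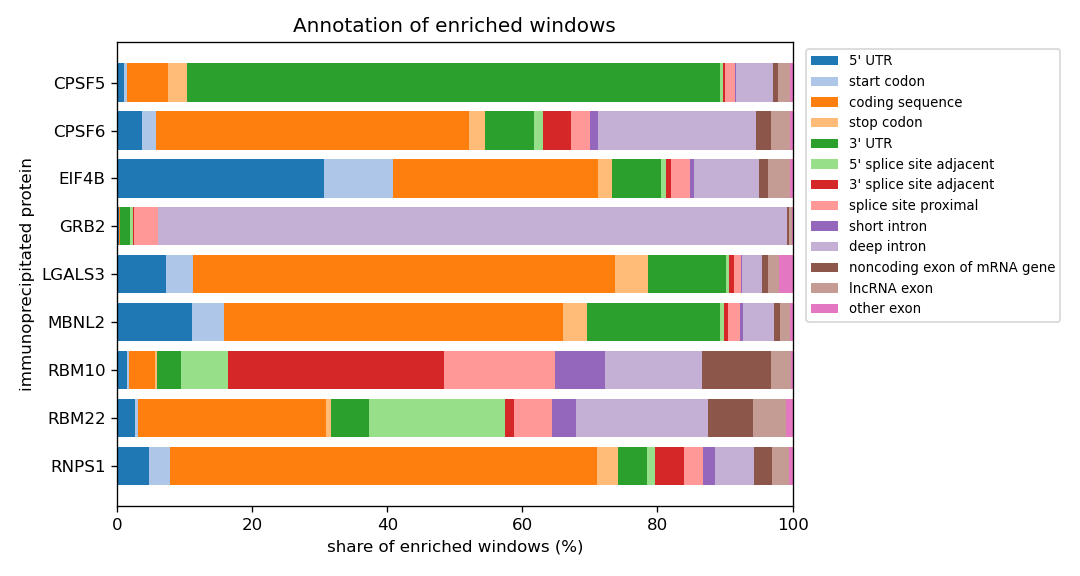
Share of enriched windows (%) in each of 13 annotated classes, one stacked bar per immunoprecipitated protein. CPSF5 stands out by 3' UTRs (78.8%), EIF4B by 5' UTRs (30.6%), GRB2 by deep introns (93.1%), RBM10 by 3' splice sites (32.0%) and RBM22 by 5' splice sites (20.1%).

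Because poly(A) sites define the ends of 3' UTRs, the place of windows inside them was examined next. CPSF5 was the one list with more windows near the annotated end than even placement gives. Of 18149 placed CPSF5 windows in 3466 genes, 17.9% were centred within 200 nt of the end against 13.1% expected, a ratio of 1.37 (adjusted permutation p = 0.0013). By position, the ratio was 1.22 in the last window, 1.52 in the window before it, 1.25 in the next and 1.04 in the one after that. CPSF6 windows were less frequent near the end than expected, at 8.71% against 12.9% (ratio 0.674), and so were those of RNPS1 (0.432), EIF4B (0.476), GRB2 (0.474) and MBNL2 (0.350), each with adjusted permutation p = 0.0013. RBM10 (0.522, adjusted p = 0.0013), RBM22 (0.531, adjusted p = 0.0090) and LGALS3 (0.322, adjusted p = 0.020) had 299, 224 and 83 placed windows in the same permutation test. The unadjusted p of 0.0010 behind most of these values is the smallest that 1000 placements can give. Every list other than CPSF5 was thus below even placement, and CPSF6 was the least depleted of them. Its ratio was 0.378 in the last window and 0.948 in the one before. Even placement assumes equal coverage along the 3' UTR, which listed windows cannot show, so a deficit here is not evidence of avoided ends.

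Genes named in the lists also had CPSF5 windows in their 3' UTRs, whose distances to the end are not given here. GSK3B, VMA21 and PAK2, reported to change poly(A) site with CFIm, reached lower-replicate log2 enrichments of 6.12, 5.27 and 5.13 there. The transcripts of CFIm itself were among them, with 6.52 in the 3' UTR of CPSF6 and 6.28 in that of NUDT21, beside 4.71 for PAPOLA, which encodes the canonical poly(A) polymerase. At a q-value of at most 0.05 in both replicates the deficits of LGALS3, RBM10 and RBM22 no longer passed the test, and neither did those of RBM10 and RBM22 at 100 nt. The end used was the most distal one of the gene, so windows at internal poly(A) sites count as far from it.

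**Figure D2:**
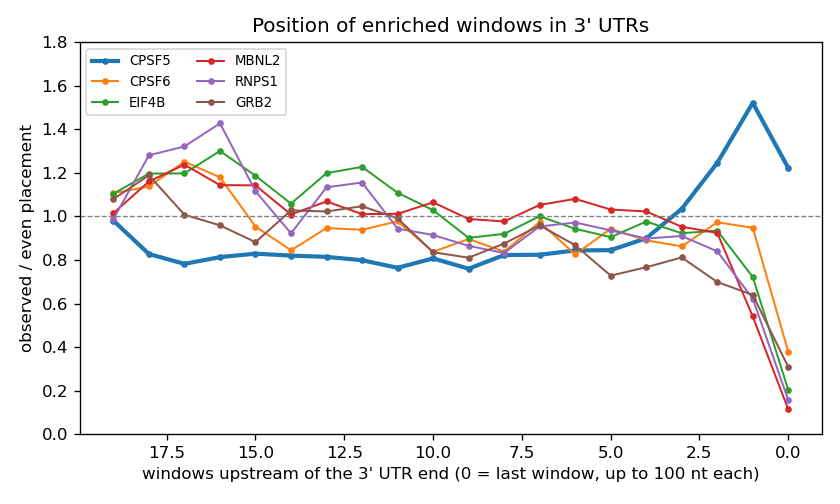
Observed over evenly placed number of windows (vertical axis, ratio) against the number of windows of up to 100 nt upstream of the 3' UTR end (horizontal axis, 0 is the last window), one line for each of 6 proteins, the dashed line at a ratio of 1. The CPSF5 line rises to 1.52 one window before the end, while the other lines fall below 1 there.

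Splice sites were examined because several of the proteins act in splicing. RBM22, a spliceosome component that contacts the 5' splice site region, had 83.0% of its windows in 5' splice site flanks in the adjacent 100 nt (interval over genes 80.9 to 84.9), against 20% for an even spread. RBM10 had 73.9% (73.0 to 74.9) adjacent at 3' splice sites and 56.8% (55.0 to 58.6) at 5' splice sites. RNPS1 and CPSF6 had 76.2% and 75.2% adjacent at 3' splice sites, and MBNL2 57.5%. At the other extreme, GRB2 had 10.8% (9.96 to 11.6) adjacent at 3' and 18.7% (18.04 to 19.2) at 5' splice sites, both below the even share (adjusted permutation p = 0.0012 and 0.0034). Examples for RBM22 were 5' splice sites of SMG5, a nonsense-mediated decay factor gene, with 53 IP reads and no input read, PGK1 with 69 and none, and CCT4 with 121 and 4. RBM10 examples at 3' splice sites were ATP2A2, a calcium pump gene, with 152 IP reads and no input read, PRPF19 with 242 and 2, and CPSF4 with 189 and none.

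Of 18 such shares, 16 differed from 20% after adjustment, an even share that may be too low where introns are short. The exceptions were CPSF5 at 3' splice sites, 21.7% (adjusted p = 0.54), and LGALS3 at 5' splice sites, where 11 windows could be used (adjusted permutation p = 0.26). The GRB2 and MBNL2 shares at 5' splice sites lost their calls with the stricter q-value, and the LGALS3 share at 3' splice sites within 300 nt.

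Inside coding exons, EIF4B and MBNL2 windows were shifted toward the upstream end. EIF4B had 39.3% in the first window of the exon and 23.3% in the last, against 31.6% expected for either, and MBNL2 had 40.5% and 28.2% against 34.5% (adjusted permutation p = 0.0030 for each). RBM10 showed the opposite order among 175 windows, with 26.3% in the first and 53.7% in the last against 39.5%. By strand, the last-window ratio was 1.49 on the plus strand (permutation p = 0.0010) and 1.15 on the minus strand (permutation p = 0.28), where the first-window ratio was 0.891 (permutation p = 0.50). RNPS1, an exon junction complex partner, had 38.3% in the first and 36.3% in the last window against 37.2% (adjusted permutation p = 0.11 and 0.17), and CPSF6 was close to even, with ratios of 1.05 and 0.946 (adjusted p = 0.031 and 0.023). CPSF5, GRB2, LGALS3 and RBM22 did not pass the test. With the stricter q-value the RNPS1 ratios of 1.04 and 0.956 passed it, as did an RBM22 ratio of 0.287 for the first window. Exons could be used only where the adjoining intron also held a listed window, which left 5634 of 96599 RNPS1 coding windows, and a window of up to 100 nt cannot resolve the deposition site of the exon junction complex. The RBM10 shifts lost their calls with the stricter q-value, which left ratios of 1.15 for the last and 0.640 for the first window.

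**Figure D3:**
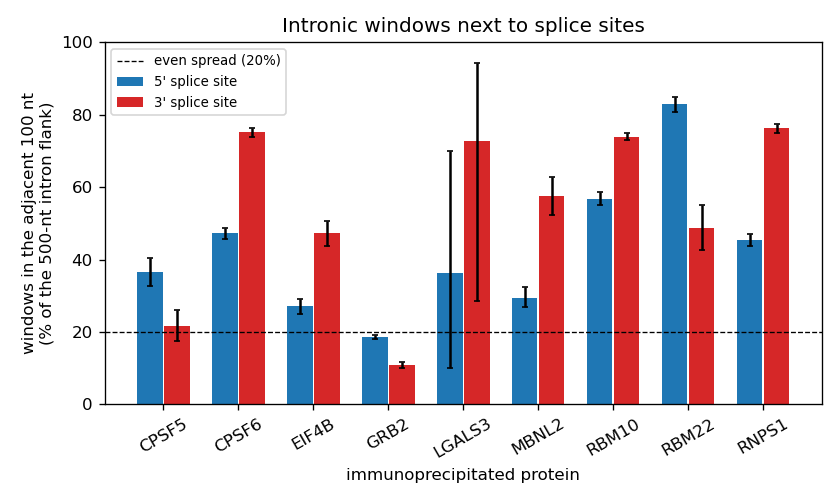
Share (%) of windows in the 500-nt intron flank that lie in the 100 nt next to the 5' splice site (blue) or 3' splice site (red), by protein, with 95% intervals from resampling genes and a dashed line at the even share of 20%. RBM22 is highest at 5' splice sites (83.0%) and RNPS1 at 3' splice sites (76.2%), and GRB2 is below the line at both.

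CPSF6 and RNPS1 shared more windows than any other pair. They had 87527 windows in common, and among windows listed for any of the other 7 proteins the odds ratio was 46.3 (interval over genes 44.0 to 49.0). CPSF6 shared far less with CPSF5, a CFIm partner, at 5468 windows and an odds ratio of 2.37 (2.22 to 2.55). High ratios joined LGALS3 with CPSF5 (25.1), MBNL2 (24.4), RNPS1 (18.8) and EIF4B (15.0), CPSF6 with RBM22 (17.8), EIF4B with MBNL2 (14.8) and RBM10 with RBM22 (10.0). Neither RNA abundance nor coverage was held equal, so ratios above 1 cannot be told apart from shared detection of abundant transcripts. GRB2 shared windows less often than independent lists with RNPS1 (0.179), CPSF6 (0.251), MBNL2 (0.664) and EIF4B (0.728). Feature class was not held equal in these ratios. Deep introns made up 93.1% of GRB2 windows and coding sequence 0.0794%. The coding share was 63.3% for RNPS1, 46.3% for CPSF6, 50.1% for MBNL2 and 30.3% for EIF4B. Such deficits can arise from class alone. Over genes the same pairs gave odds ratios of 4.04, 4.89, 1.39 and 2.59. GRB2 and LGALS3 had 18 windows in common and did not differ from independence (odds ratio 1.12, Fisher's exact test, adjusted p = 0.71), although the ratio was 5.02 (1.61 to 12.1) with the stricter q-value.

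Of 36 pairs, 31 had an odds ratio above 1 and 4 below 1 with intervals that exclude 1. Over genes, 35 pairs were above 1 and 0 below, with 34.5 for CPSF6 and RNPS1, 16.4 for RBM10 and RNPS1, and 14.5 for EIF4B and MBNL2. RNA abundance was not held equal over genes either, so these ratios do not by themselves show shared binding. The odds ratio depended on the background. With all 9 lists as the background, which adds windows listed for 1 protein alone as evidence against sharing, CPSF5 and CPSF6 gave 0.451, and 15 pairs were called below 1, the 4 of the first analysis among them. Among 3' UTR windows only, CPSF5 and CPSF6 gave 1.05 and lost the call, CPSF5 and RNPS1 gave 0.738, GRB2 and MBNL2 1.51 (0.999 to 2.28), and CPSF6 and RNPS1 19.4. The ratio of EIF4B and GRB2 lost its call there (0.834), with the stricter q-value (0.757) and when windows within 100 nt counted as shared (0.956).

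**Figure D4:**
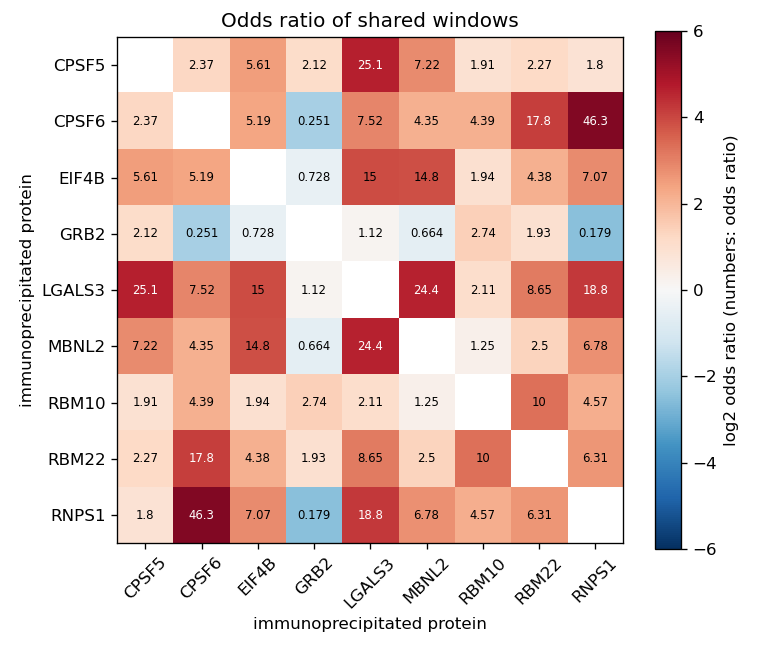
Odds ratio of shared windows for each pair of the 9 proteins (numbers), colored by its log2 value from -6 (blue) to 6 (red). CPSF6 with RNPS1 is highest (46.3), and GRB2 with RNPS1 lowest (0.179).

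Some windows, most of them in introns and with no listed window touching them, were strong in several lists at once. An intron window of BTBD2 (chromosome 19, 1998553 to 1998650) held 11356 IP reads and 1 input read for CPSF5, 7879 and 3 for GRB2, 1084 and 1 for LGALS3, and 428 and 0 for MBNL2. A window of TTC3 near a 3' splice site (chromosome 21, 37095150 to 37095249) was strong for CPSF5, GRB2 and LGALS3, and an intron window of ITPR2 (chromosome 12, 26441968 to 26442065) for those and MBNL2. An intron window of PRKCA (chromosome 17, 66757027 to 66757126) held 2349 IP reads for RBM22, 1514 for RBM10, 1038 for EIF4B and 874 for CPSF6. ETV5 (chromosome 3, 186107741 to 186107839) and KRT19 (chromosome 17, 41526939 to 41527035) had intron windows shared among CPSF6, EIF4B and RBM22, the ETV5 window also with RBM10. UBTD2 had one near a 5' splice site shared among EIF4B, RBM10 and RBM22, ITFG1 an intron window shared by EIF4B and RBM10, and SPIN4 touching coding windows shared by EIF4B and RBM10, 1 of them also with RBM22. FRAS1 and NME5, strong for RBM22 at 8.10 and 7.19, had 1 window each. NBPF14, strong for CPSF6 at 7.11, and RPL30, strong for EIF4B at 8.83, are multi-copy genes and uncertain.

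Fixed gene lists were compared with all genes that other proteins' lists held, which asks whether a protein bound transcripts of a functional group more often than others. Of 144 tests of 16 lists, 41 were above and 11 below the background after adjustment over all tests, and 45 and 11 when adjusted over each protein's lists alone. Against genes with a matched number of windows, 15 were above and 8 below, so group differences named here are given with the matched result. Window number mixes gene length with RNA abundance, so matching on it holds neither equal, nor the intron content of a gene. Calls in either direction may therefore reflect abundance or gene structure. The adjusted p of 0.0076 in the matched test is the smallest its permutations can give.

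Replication-dependent histone genes were listed for LGALS3 and MBNL2 more often than matched genes. Of 47 replication-dependent histone genes, 28 had an LGALS3 window, 59.6% against 2.19% of matched genes, and 42 of 47 had an MBNL2 window, 89.4% against 53.1% of matched genes (matched adjusted permutation p = 0.0076 for both). GRB2 was listed for 1 and RBM10 for 2 of 47 histone genes, below the matched background (adjusted permutation p = 0.0076 and 0.014). Introns held 97.35% of GRB2 windows and coding sequence only 3.9% of RBM10 windows, and matching took no account of feature class. Genes with few or no introns can fall below the background for that reason alone. These counts therefore do not show avoidance of histone RNA. The same limit applies to the other GRB2 deficits among the gene lists. Strong histone windows lay in 5' UTRs, with a log2 enrichment of 4.23 in H2BC18 for LGALS3 and 6.16 in H2AC20 for MBNL2. LGALS3 was also above the matched background for ribosomal proteins (26 of 79), chaperones (10 of 24), hnRNP proteins (8 of 25), translation initiation factors (8 of 29), mitochondrially encoded genes (5 of 15) and glycolysis (4 of 17), each with adjusted permutation p = 0.0076. Examples were RPL23A at 3.13, the chaperone HSP90AA1 at 3.31, PABPC1 at 2.71 and LDHB at 2.60. Histone and ribosomal protein genes are uncertain because of near-identical copies. RNA abundance was not controlled, so the LGALS3 calls cannot be told apart from high abundance of these groups. With a q-value of at most 0.05 in both replicates, the LGALS3 calls against the unmatched background were lost for hnRNP, initiation factor, chaperone, glycolysis and mitochondrial genes. The call for SR protein genes (4 of 17) was lost with the matched background too.

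Ribosomal protein genes were listed for RBM22 and RBM10 more often than matched genes, and SR protein and translation initiation factor genes for RBM22. RBM22 was listed for 14 of 17 SR protein genes, 82.4% against 38.3% of matched genes, 21 of 29 translation initiation factor genes (72.4% against 38.0%) and 46 of 79 ribosomal protein genes (58.2% against 19.8%), all above the matched background (adjusted permutation p = 0.0076). Examples were EIF3J at a 5' splice site, with 44 IP reads and no input read, and an exon of SRSF5 at a log2 enrichment of 2.89. RBM10 was listed for 69 of 79 ribosomal protein genes, 87.3% against 46.7% of matched genes (matched adjusted permutation p = 0.0076). Core spliceosome (14 of 30), hnRNP (16 of 25) and exon junction complex and decay genes (7 of 18) did not pass the matched test for RBM22 (adjusted permutation p = 0.59, 0.12 and 0.92). The RBM10 calls for core spliceosome (25 of 30), hnRNP (21 of 25), initiation factor (26 of 29), SR protein (14 of 17), exon junction complex and decay (14 of 18) and glycolysis genes (13 of 17) did not pass the matched test (adjusted permutation p = 0.13, 0.25, 0.072, 0.28, 0.26 and 0.23).

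The genes of small nuclear and 7S RNAs, a mixed list that also holds vault RNAs and U3, were listed for RBM22 and RBM10 more often than matched genes. RBM22 was listed for 13 of 54 small nuclear and 7S RNA genes against 1.74% of matched genes, and RBM10 for 14 of 51 against 6.23% (adjusted permutation p = 0.0076 for both). The strongest RBM22 members were U6 copies, with 505 IP reads and 3 input reads at RNU6-49P, and the strongest RBM10 members U2 copies, with 19447 and 424 at RNU2-4P. CPSF6 (7 of 59), EIF4B (6 of 58) and GRB2 (0 of 57) were below the matched background (adjusted permutation p = 0.0076). GRB2 alone was listed for U3, which the count leaves out because only genes listed for another protein were measured. Without matching, RBM22 did not differ from the background (24.1% against 23.2%, Fisher's exact test, adjusted p = 0.97). Without matching, RBM10 was below the background (27.5% against 45.7%, Fisher's exact test, adjusted p = 0.032), so the direction of that call turned with matching. RNPS1 (16 of 56), MBNL2 (9 of 58) and CPSF5 (13 of 48) were below the unmatched background only. These copies cannot be told apart by short reads and are uncertain.

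The mitochondrially encoded genes had windows for 7 of 15 members with RBM22 (matched adjusted permutation p = 0.0076) and 0 of 15 with GRB2 (0.027). GRB2 was also below the matched background for core spliceosome genes (13 of 30, adjusted permutation p = 0.033) and ribosomal protein genes (27 of 79, adjusted p = 0.038). Without matching, these 2 calls (Fisher's exact test, adjusted p = 0.84 and 0.062) and the RBM22 call for mitochondrial genes (0.13) did not pass. CPSF5 was listed for 9 of 9 genes reported to change poly(A) site with CFIm, among them DICER1 and FHL1, against 62.2% of other genes (Fisher's exact test, adjusted p = 0.046, matched adjusted p = 0.23). For cleavage and polyadenylation factors, CPSF6, EIF4B and RNPS1 were listed for 21 of 21 and CPSF5 for 16 of 21, with no call for any protein. MBNL family and target genes gave no call either, with 11 of 15 listed for MBNL2 (Fisher's exact test, adjusted p = 0.75). Nuclear long noncoding RNAs were above the background for RBM22, 6 of 8 (Fisher's exact test, adjusted p = 0.010, matched 0.072). When adjusted over each protein's lists alone, CPSF5 (8 of 8, Fisher's exact test, adjusted p = 0.041) and LGALS3 (2 of 8, 0.037) passed too, but neither passed the matched test (adjusted permutation p = 0.26 and 0.21). NEAT1, the paraspeckle RNA, held 2284 IP reads and 48 input reads in its strongest RBM10 window. The genes of the assayed proteins as a list gave no call when adjusted over all tests. When adjusted over each protein's lists alone, LGALS3 passed (2 of 8, Fisher's exact test, adjusted p = 0.037), but not in the matched test (adjusted permutation p = 0.19).

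The gene of each immunoprecipitated protein was then examined, since a tagged transgene of coding sequence alone would give coding windows without UTR or intron windows. The labels describe no construct. MBNL2 had 15 coding, 2 5' UTR and 7 intron windows in its own gene and none in its 3' UTR, and the coding windows held 617765 IP reads and 128310 input reads, 22.9% of the IP and 23.6% of the input reads in its listed windows. RNPS1 had 13 coding, 6 5' UTR and 6 intron windows and none in its 3' UTR, with 528077 coding IP and 30219 input reads. LGALS3 had 6 coding, 1 5' UTR and 4 intron windows in its own gene, with 9152 coding IP and 5370 input reads and a median lower-replicate log2 enrichment of 1.36, and no other protein was listed for that gene. In contrast, CPSF5 had 13 windows in the 3' UTR of NUDT21 and 2 in its coding sequence, and CPSF6 had 11 and 17 in its own gene. GRB2 had 40 intron windows in its own gene and no coding window, RBM10 40 intron windows and 1 coding window, EIF4B 3 coding windows and RBM22 none.

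Coding windows of MBNL2 and RNPS1 were also among the strongest of the LGALS3 list. MBNL2 held 14 coding windows there, with 12862 IP and 87 input reads and a median log2 enrichment of 6.87, and the strongest (chromosome 13, 97276336 to 97276409) had 459 IP reads and no input read. Besides these, 2 intron windows and 1 5' UTR window of MBNL2 were listed for LGALS3. RNPS1 held 1 5' UTR window and 12 coding windows there, the coding windows with 4512 IP and 123 input reads and a median of 4.84. The strongest covered the start codon (chromosome 16, 2262323 to 2262422), with 638 IP reads and 8 input reads. Coding windows of the 2 genes also occurred in other lists. The RNPS1 list held 14 coding, 7 intron and 3 5' UTR windows of MBNL2, with 7707 coding IP and 940 input reads and a median of 2.74. The MBNL2 list held 9 coding and 2 intron windows of RNPS1, with 1235 coding IP and 245 input reads and a median of 2.53. No 3' UTR window of either gene was listed for LGALS3. For MBNL2 none was listed for any of the 9 proteins, so that absence is not particular to LGALS3. The 3' UTR of RNPS1 had 8 windows for CPSF5, 4 for MBNL2 and 2 for EIF4B. The authors' labels do not say which lines carried a tagged protein, so these counts describe reads at the genes and not their origin.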

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

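Of the alternatives, leaving out the assayed proteins' own genes and leaving out windows strong in several lists were chosen after seeing the data, and the others were planned. Feature composition kept its direction in 62 of 63 comparisons, positions near 3' ends kept their call in 31 of 36, splice site flanks in 51 of 54, exon ends in 31 of 36, window overlaps in 219 of 252 and gene lists in 153 of 208. No paired analysis was possible because the tables give only the lower and higher replicate value of each window, without replicate labels, and read counts summed over replicates. Leaving out 1 replicate at a time, motifs and poly(A) signals with their alternatives (no genome sequence), and 25 or 50 nt at splice sites (finer than the windows) were not run. The most distal gene end was already the main setting, since no other ends were given. Library depth was not known, and positions in the LGALS3 list rest on few windows.

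Stricter q-values remove windows by construction. At most 0.05 left 24444 for CPSF5, 77336 for CPSF6, 148159 for GRB2, 276 for LGALS3, 23443 for MBNL2, 8983 for RBM10, 3016 for RBM22 and 96432 for RNPS1. At most 0.01 left 15478 for CPSF5, 38639 for CPSF6, 35873 for EIF4B, 81814 for GRB2, 118 for LGALS3, 13013 for MBNL2, 3455 for RBM10, 1186 for RBM22 and 60059 for RNPS1. Merging joins touching windows and left 19630 regions for CPSF5, 91865 for CPSF6, 36149 for EIF4B, 93737 for GRB2 and 91029 for RNPS1, and a minimum of 20 IP reads left 25203 MBNL2 windows. Coding windows in the own gene fell to 0 (CPSF5, RBM10), 1 (LGALS3) and 10 (CPSF6) at a q-value of at most 0.05, and to 1 (CPSF5) with the read minimum. Weighted by IP reads, the LGALS3 coding share lay -0.248 points from the other lists, and the cause was not tested.

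For the following values the cause was not tested. At a q-value of at most 0.05, calls near 3' ends were lost for LGALS3 (0.737), RBM10 (0.626) and RBM22 (0.608), and within 100 nt for RBM10 (0.677) and RBM22 (0.476). At 5' splice sites the stricter q-value ended the calls of GRB2 (ratio 0.954) and MBNL2 (1.23), and a 300-nt flank that of LGALS3 at 3' splice sites (1.51). At exon ends it ended those of RBM10 (last 1.15, first 0.640) and gave calls for RBM22 (first 0.287) and RNPS1 (last 0.956, first 1.04). It left 2 pairs of lists below independence. Odds ratios crossed 1 for MBNL2 and RBM10 (0.894, and 0.947 with the read minimum), and for GRB2 and RBM22 when windows within 100 nt counted as shared (0.952). Among 3' UTR windows they crossed 1 for RBM10 with CPSF5 (0.540) and LGALS3 (0.336), for CPSF5 with RBM22 (0.749) and RNPS1 (0.738), and for GRB2 with MBNL2 (1.51). The LGALS3 share of SR protein genes lay -0.839 points from the background at the stricter q-value. Matching genes on window number left 15 gene list tests above the background, and put small nuclear and 7S RNAs 9.77 points above it for CPSF5, with no call, and 21.2 for RBM10.

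The union of all lists as background counts windows listed for 1 protein alone against sharing, which left 19 pairs above and 15 below independence. Odds ratios then fell below 1 for CPSF5 with CPSF6 (0.451), EIF4B (0.928), GRB2 (0.0309), RBM10 (0.328), RBM22 (0.585) and RNPS1 (0.316), for RBM10 with EIF4B (0.641), GRB2 (0.0473), LGALS3 (0.910) and MBNL2 (0.505), and for GRB2 with RBM22 (0.0392). The ratio of GRB2 and LGALS3 was 0.0200.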

Other observations

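The tests of read profiles over genes, of endogenous MBNL2 mRNA, of GRB2 density by input reads and of GRB2 splice site flanks were chosen only after the result was seen, and the other tests were planned. The median GC content was 70.5% in EIF4B windows of 5' UTRs and 56.0% in those of coding sequence, 34.3% in CPSF5 windows of 3' UTRs against 52.0% in MBNL2 windows of 3' UTRs, and 63.0% in RBM22 windows next to 5' splice sites. Deep intron windows had 41.0% for GRB2 and 57.0% for EIF4B, and class and protein were not tested apart. The CPSF5 list also held 8 windows in the 3' UTR of RNPS1, with 869 IP reads, and the strongest reached a log2 enrichment of 6.61.

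Coding windows of MBNL2 and RNPS1 in the LGALS3 list may come from RNA or reads of the MBNL2 and RNPS1 IP libraries. The planned test, on windows with at least 50 expected reads and a log2 enrichment of at least 4, had 0 windows to test, and looser minimums tried afterwards pointed different ways, from 6 of 6 to 19 of 47 listed for MBNL2 and from 3 of 3 to 13 of 75 for RNPS1. The LGALS3 to RNPS1 ratio of IP reads varied 1.46-fold over 13 windows, against 2.96-fold relative to RNPS1 input reads, which fits carry-over only under a limit that was set and once revised after these ratios were seen. The ratio to MBNL2 varied 3.26-fold over 16 windows, against 4.58-fold relative to MBNL2 input reads and 4.49-fold relative to RNPS1 IP reads, and cannot tell, although the limit as first written would have excluded MBNL2 carry-over. Endogenous MBNL2 mRNA stays open too, since 0 of its 3' UTR windows were listed but chance gives that with probability 0.126, and no other biological explanation was tested.

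Windows strong in several lists kept mostly to 2 sets of proteins defined from these data. One held CPSF5, GRB2, LGALS3 and MBNL2, the other CPSF6, EIF4B, RBM10 and RBM22. RNPS1 was left out of both, and 20 of 25 such windows shared among the other proteins lay within a set. The strong windows that RNPS1 shared were in H2BC4 with EIF4B and in NCOR1 and NUCB2 with CPSF6, all members of the second set. One preparation or batch per set could account for this, and 30.99% of shared windows touched another listed window (interval 15.7 to 48.5), against 96.9% of 5860 windows strong in 1 list. That value lies between the planned limits and cannot tell. A shared binding preference within sets is also open, as the median odds ratio was 4.78 within and 2.44 between sets, a ratio of 1.96 that lies between the planned limits. These medians leave out RNPS1, whose odds ratio with CPSF6 was the highest of all pairs (46.3). Medians with RNPS1 in the second set were not computed, so the ratio may depend on leaving it out. The labels name no batches, so neither explanation was separated further. Because the sets were drawn from these same data, the count of 20 of 25 describes the sets and does not test them.

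Whether the intronic GRB2 list may come from unspliced RNA sampled along introns without a preferred place stays open, since 10.8% of windows in 3' splice site flanks and 18.7% in 5' flanks were adjacent to the site, both below the even share of 20%. Genomic DNA in the IP libraries was not borne out, because genes over 100 kb with most input reads in the other lists had 5.72 times the GRB2 windows per kb of those with fewest (interval 4.63 to 7.11). A planned density test gave 0.000724 and was void, because the annotation covers little beyond the listed genes. Few input reads alone did not account for the introns, which made up 89.1% of 27058 windows with at least 5 input reads and 97.3% of all. Whether GRB2 itself or a protein recovered with it bound this RNA was not tested.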
